A study of Mus musculus with 5 samples.

How the data were processed

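Gene expression was measured on 5 Affymetrix microarrays hybridised with cDNA from mouse embryonic fibroblasts grown under a 3T3 schedule, a routine of serial passaging, and collected at passage 40. The labels put 3 arrays in an Mdr2 knockout group (replicates 1, 2 and 3) and 2 in a wild-type group (replicates 2 and 3). Per the labels' protocols, total RNA was isolated on columns, amplified with a whole-transcriptome kit and labelled with biotin. Per the submitters' processing notes, the arrays were processed with Affymetrix Expression Console. Its version and the summary and normalization method are not given in the sources used here. The values deposited by the authors are on a log2 scale, one per probe set and array, and were used as deposited. A second deposited table of the same arrays held the same log2 values, with 0 differences among 35556 probe sets, so exchanging the tables changes nothing.

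Of the 35556 probe sets, 7115 control probe sets were left out. Of the remaining 28441, 25004 carried 1 gene symbol, 2 carried several and 3435 carried none. Symbols were brought up to date through a table of mouse genes of assembly GRCm38.p6, used for names alone. It named 22271 probe sets through a transcript accession and 1969 through a current or older symbol, and 764 kept the symbol of the array annotation. The brightest probe set by the mean over all 5 arrays stood for each gene, which gave 21630 genes, 1822 of them with more than 1 probe set. Coordinates are those of the array annotation. They are taken as mouse build NCBIM37, since 2759 of 2955 annotation rows that state a position in that build overlap their own coordinates.

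The number of arrays limits the precision. The median log2 signal of the tested genes lay between 4.27 and 4.33 on every array. The 45 antigenomic probe sets, which match no mouse sequence, had a median of 2.14 on every array, and their 95th percentile lay between 5.71 and 6.08. No detection call was used, and a fold change against a group near that background understates the change. Of the tested genes, 7670 had 5 distinct values and 1589 had equal values on all 5 arrays. Genes without any spread lower the prior variance that limma estimates: the prior standard deviation was 0.0282 with them and 0.0843 without them. The prior had 0.626 degrees of freedom with them and 1.44 without them.

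Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 3 residual degrees of freedom, no block), with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values of single genes come from this fit, and errors given with a log2 fold change are its moderated standard errors. Gene lists, chromosomes and the region within 10 Mb of Abcb4 were tested with limma's camera at a preset inter-gene correlation of 0.01, and a Fisher exact test, two-sided, compared the share of called genes near Abcb4. The comparison, thresholds, 34 gene lists and most alternatives were fixed before the data were examined. The list members Trim16l, Rian, Mirg, Kcnq1ot1 and Igtp had no matching probe set. A planned Gene Ontology test was not run, since the annotation used here pairs no genes with such terms.

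Genes were named by a rule fixed beforehand. It took Abcb4, Abcb1a and Abcb1b. It took the 12 largest rises and 12 largest falls among genes with an adjusted p under 0.05, no overlap between groups and a mean in the higher group above the median of all genes, without predicted, clone, olfactory, vomeronasal or small RNA symbols. It took up to 4 members per list past the threshold, the largest members of the oxidative stress and lipid lists that missed it, the sex-linked markers, and up to 4 of the brightest called genes of each chromosome past its threshold. A gene that this rule takes is not reported here. Every other gene named was chosen after its values were seen, including the members of other lists that missed the threshold, Trp53, and the positional transcription factors of the closing section.

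On simulated data made from the real means and spreads of the 21630 genes, with 200 genes changed in each of 10 data sets, limma recovered 47.0% of genes changed by 1 on the log2 scale, 75.2% of those changed by 2 and 93.6% of those changed by 4. It also called 12.8 unchanged genes per data set on average, beside 315, 504 and 618 changed genes recovered over all 10 data sets. With genes of equal values left out, it recovered 58.2%, 84.9% and 97.1% and called 9.3 unchanged genes per data set. Camera called 0 of 340 unshifted lists and all 10 lists lowered by 1. These simulations draw genes independently, so they do not test camera on correlated genes.

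The alternatives were a second quantile normalization, subtraction of array medians, removal of genes below the 40th percentile of mean level, the mean of all probe sets of a gene, trended and robust prior variances, array weights, the replicate number as a block, leaving out each array, a threshold of 0.01, limma's treat against a 1.2-fold change, an estimated inter-gene correlation, fry, chromosomes tested on the brighter part of the genes, and 5 and 20 Mb around Abcb4. Further settings, 5 in number, were added after the data had been seen: leaving out genes with equal values on all arrays, testing only genes above the median level or above a log2 signal of 6, joining the 40th percentile filter with trended and robust variances, and subtracting chromosome medians before the list tests. Figures were drawn with matplotlib.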

Results

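Expression profiles were compared between mouse embryonic fibroblasts labelled Mdr2 knockout and wild type at passage 40. Mdr2 is the older name of Abcb4, which encodes the phosphatidylcholine translocator of the hepatocyte canalicular membrane. The data comprised 5 arrays, 3 labelled knockout and 2 wild type, with 21630 genes tested. Nothing in the labels says whether the replicates were separate cultures or embryos, so the p-values measure only the spread between these samples, which may be technical.

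Abcb4 itself was not lower on the arrays labelled knockout. Its log2 signal was 6.002, 4.628 and 5.744 on knockout replicates 1, 2 and 3, against 4.054 and 3.949 on wild-type replicates 2 and 3. The group means were 5.458 ± 0.73 (SD, n = 3) and 4.001 ± 0.07 (SD, n = 2), a log2 fold change of 1.46 ± 0.50 (SE) that missed the threshold (limma adjusted p = 0.358). The probe set, 10519578, is annotated to chromosome 5, 8893717 to 8959226 (NCBIM37). The sources used here do not state which part of the gene was disrupted, so a probe outside that part would check nothing. Its signal lay below the 95th percentile of the antigenomic background probe sets on every array except knockout replicate 1 (5.97 there, 5.71 to 6.08 over all arrays), so it was not clearly above background and checks the labels weakly. The direction of its signal went against the label, and every direction below is that of the arrays labelled knockout. Its neighbouring paralogues Abcb1a and Abcb1b, which encode multidrug efflux pumps, had log2 fold changes of 0.39 ± 0.11 and 0.57 ± 0.40 (SE), with adjusted p-values of 0.281 and 0.554.

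The groups also differed in sex-linked transcripts. Xist, the RNA that coats the inactive X chromosome, was 21.2-fold higher on the arrays labelled knockout, at 7.48 ± 0.18 (SD, n = 3) against 3.08 ± 0.14 (SD, n = 2; adjusted p = 0.0250). The Y-linked genes Ddx3y and Eif2s3y were lower there by log2 fold changes of -4.40 ± 0.16 and -4.99 ± 0.22 (SE; adjusted p = 0.0267 and 0.0296). The Y-linked Kdm5d and Uty had log2 fold changes of -2.58 and -2.47 and missed the threshold (adjusted p = 0.0675 and 0.148), though Kdm5d passed on quantile normalization (adjusted p = 0.0216). Genotype label and sex-linked expression therefore changed together across all 5 arrays, and each difference below was measured between groups that differed in both.

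**Figure D1:**
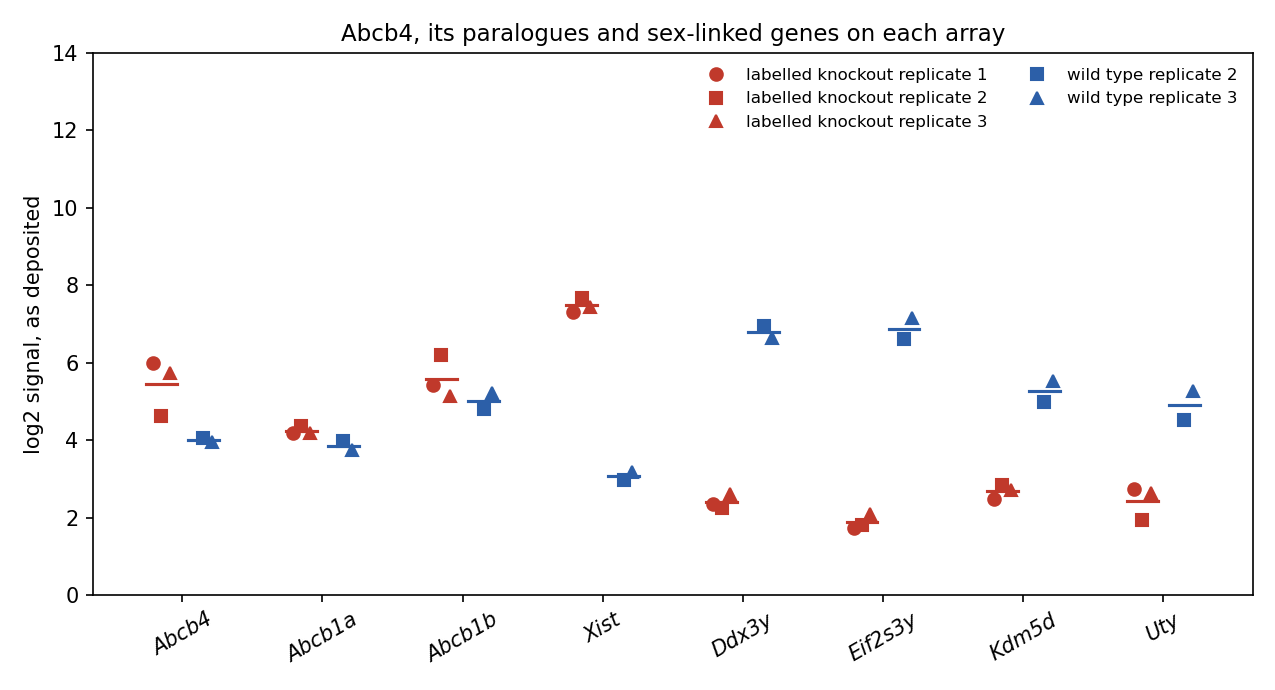
Log2 signal of Abcb4, its paralogues Abcb1a and Abcb1b, and 5 sex-linked genes on each of the 5 arrays, with symbols for replicates and horizontal bars for group means. Abcb4 lies between 4.628 and 6.002 on the arrays labelled knockout and at 4.054 and 3.949 on the wild-type arrays, and Xist and the Y-linked genes separate the groups in opposite directions.

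Sfrp2, a secreted Wnt modulator, rose 169-fold on the arrays labelled knockout, from 3.53 ± 0.23 (SD, n = 2) to 10.93 ± 0.27 (SD, n = 3; adjusted p = 0.0240). Cyp1b1, a cytochrome P450, rose by a log2 fold change of 6.46 ± 0.22 (SE), and Mme, the membrane endopeptidase neprilysin, by 6.07 ± 0.21 (SE). Vit, which encodes the matrix protein vitrin, fell by 6.30 on the log2 scale, and the imprinted gene Peg3 by 6.17, from 9.60 ± 0.23 (SD, n = 2) to 3.43 ± 0.07 (SD, n = 3).

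Other large rises were those of Mab21l2 (log2 fold change 5.24), Enpp2 (4.51), which encodes autotaxin, a lysophospholipase D, Dkk3 (4.08), Rsph9 (3.60), Igf1 (3.47), Mecom (3.46) and Baiap2l1 (3.06), and Hoxc10 rose 16.0-fold. Other large falls were those of the transcription factor gene Tfap2b (-5.30), the aldehyde dehydrogenase Aldh3a1 (-5.15), Ccdc68 (-5.11), the G protein subunit Gnai1 (-4.91), the growth factor binding protein Igfbp2 (-4.16), Perp (-2.83) and Eda2r (-2.76). A second, dimmer probe set of Cyp1b1 gave a log2 fold change of 2.62 and one of Mecom 0.56, both in the same direction as the brighter one. The lower group lay near background for most of these genes, so the fold changes are compressed. With a robust prior variance the calls on Mab21l2, Baiap2l1, Aldh3a1 and Igfbp2 ended (adjusted p = 0.0582, 0.0662, 0.0569 and 0.0544), as did that on Baiap2l1 with a trended one (adjusted p = 0.0538).

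In all, 65 genes passed the adjusted p of 0.05, 33 higher and 32 lower on the arrays labelled knockout, and 46 of them differed at least 2-fold (27 higher, 19 lower). At an unadjusted p under 0.05 there were 2952 genes. The count moved with the genes admitted to the test: 270 genes passed when the dimmest were left out, 61 of the 65 among them. It rose to 359 when the genes with equal values on all arrays were left out, a setting chosen after seeing the data. With limma it was 0 without knockout replicate 1 (2297 at an unadjusted p under 0.05), 2 without knockout replicate 2, 0 without knockout replicate 3 (2196 at an unadjusted p under 0.05), 189 without wild-type replicate 2 and 335 without wild-type replicate 3. Of the 65 genes, 18 were among those 189 and 34 among those 335, and the calls on Cyp1b1, Mme and Xist ended without wild-type replicate 2 (adjusted p = 0.0582, 0.0580 and 0.0536).

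Targets of p53, the tumour suppressor that halts the cell cycle after damage, lay lower on the arrays labelled knockout. Of 35 measured targets 3 fell and 32 did not pass the test, and 19 were lower when adjusted over the list alone. Those that fell were Perp, Eda2r and the repair endonuclease gene Ercc5 (-1.24 ± 0.07, SE; adjusted p = 0.0493). Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, was at 7.22 ± 0.67 (SD, n = 3) against 10.85 ± 0.52 (SD, n = 2; adjusted p = 0.132). The list's median log2 fold change was -0.77 (camera adjusted p = 4.41e-10; adjusted p = 0.585 with an estimated correlation). Trp53 itself had a log2 fold change of 0.08 ± 0.21 (SE; adjusted p = 0.886). In the senescence and immortalisation list 0 of 27 members passed, with 7 higher and 5 lower when adjusted over the list alone. Its member Cdkn2a, which encodes the inhibitors p16 and p19ARF, had a log2 fold change of 1.99 ± 0.17 (SE; adjusted p = 0.0675) and passed on quantile normalization (adjusted p = 0.0154).

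Proliferation genes lay higher as a list on the arrays labelled knockout, although 0 of 42 members passed limma's test singly or when adjusted over the list alone, and 6 were higher at an unadjusted p under 0.05. The list's median log2 fold change was 0.76 (camera adjusted p = 9.44e-07; adjusted p = 0.816 with an estimated correlation). Its median difference from the wild-type mean was 0.19, 1.25 and 0.81 on knockout replicates 1, 2 and 3. Among 47 DNA repair genes 0 passed singly or adjusted over the list alone, and the list did not shift (camera adjusted p = 0.493).

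Among homeobox genes, those that passed the test belong to Hox group 10, whose members pattern the posterior body and the limbs. Of 39 measured Hox genes 3 rose and 36 did not pass, with 10 higher and 1 lower when adjusted over the list alone. The genes that rose were Hoxc10, Hoxd10 (2.53 ± 0.12, SE) and Hoxa10 (1.96 ± 0.06, SE). The list shifted upward (camera adjusted p = 0.00112; adjusted p = 0.585 with an estimated correlation), with a median log2 fold change of 0.05 and a mean of 0.50, since many members lay at background on every array. Its estimated correlation was -0.0046, below the preset 0.01, yet the unadjusted camera p rose from 0.000164 to 0.0214. Correlation between members is therefore not what raised it. Among 24 imprinted genes Peg3 fell and 23 did not pass, with 3 higher and 7 lower when adjusted over the list alone. That list did not pass with camera (adjusted p = 0.112) but passed with fry (adjusted p = 0.0298).

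Genes of oxidative phosphorylation lay slightly lower and genes of glycolysis and the hypoxia response higher on the arrays labelled knockout. Of 46 oxidative phosphorylation genes 0 passed limma's test singly or adjusted over the list alone, with 23 lower at an unadjusted p under 0.05, 42 on the lower side and a median log2 fold change of -0.30 (camera adjusted p = 9.63e-10; adjusted p = 0.816 with an estimated correlation). Of 33 glycolysis and hypoxia genes 0 passed singly or adjusted over the list alone, and the median was 0.66 (camera adjusted p = 0.00245; adjusted p = 0.816 with an estimated correlation). Knockout replicate 2 stood apart for this list: its median difference from the wild-type mean was -0.08, against 1.09 and 1.19 on replicates 1 and 3. The list's call ended without knockout replicate 1 (adjusted p = 0.0566) and without wild-type replicate 3 (adjusted p = 0.141). The hypoxia target Car9, for example, was at 7.70, 5.11 and 8.07 on the knockout replicates and at 3.71 and 3.77 in wild type (adjusted p = 0.357).

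Antioxidant enzymes changed little as a group on the arrays labelled knockout. Of 36 measured members only Gpx7, which encodes a peroxidase of the endoplasmic reticulum, rose (7.78 ± 0.18, SD, n = 3, against 5.30 ± 0.09, SD, n = 2; adjusted p = 0.0402, and 0.0582 with a robust prior variance). When adjusted over the list alone 3 were higher and 6 lower, and the list missed the threshold (camera adjusted p = 0.0708), which it passed downward without wild-type replicate 2 (adjusted p = 0.0291; adjusted p = 0.816 for all arrays with an estimated correlation). The plasma glutathione peroxidase gene Gpx3 was at 6.75, 3.63 and 6.24 on the knockout replicates against 2.74 and 3.03, a log2 fold change of 2.66 ± 1.14 (SE; adjusted p = 0.481). Sod3 had a log2 fold change of 1.24 and Gsr of -1.09 (adjusted p = 0.150 and 0.174).

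Targets of NRF2, the transcription factor of the oxidative stress response, had 0 of 35 members past the test and 6 lower when adjusted over the list alone (camera adjusted p = 0.0911). Their largest differences were those of Ephx1 (-2.20, adjusted p = 0.0675), Gsta4 (-2.04, adjusted p = 0.178), Gstm2 (-1.75, adjusted p = 0.158) and Nqo1 (-1.26, adjusted p = 0.156). Among 46 aldehyde and xenobiotic oxidoreductases Cyp1b1 rose and Aldh3a1 fell, with 4 higher and 7 lower when adjusted over the list alone (camera adjusted p = 0.820). That list's median and mean differed in sign (-0.003 and 0.01). None of 24 glutathione S-transferases or 26 oxidant-producing enzymes passed, singly or adjusted over the list alone, and neither list shifted (camera adjusted p = 0.697 and 0.835).

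Lipid metabolism genes mostly did not pass. Fatty acid oxidation genes had a median log2 fold change of -0.20 (camera adjusted p = 0.0439; adjusted p = 0.816 with an estimated correlation), yet the 1 of 36 members that passed, Etfdh, rose by 0.21 ± 0.01 (SE). When adjusted over the list alone 2 were higher and 6 lower. The call on Etfdh was lost once genes with equal values were left out (adjusted p = 0.117), and the list's call on quantile normalization (adjusted p = 0.157), on subtraction of array medians, on removal of dim genes, on the mean of all probe sets (adjusted p = 0.0519) and without knockout or wild-type replicate 3 (adjusted p = 0.216 and 0.444).

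Of 41 fatty acid and triglyceride synthesis genes 0 passed, with 3 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0708). The list passed upward on quantile normalization (adjusted p = 0.0106), on subtraction of array medians (adjusted p = 0.0155) and without knockout replicate 3 (adjusted p = 0.0210). Those used the preset correlation, and its adjusted p was 0.816 with an estimated correlation. The stearoyl-CoA desaturase gene Scd1 had a log2 fold change of 2.78 ± 0.76 and the adipogenic regulator Pparg of 1.98 ± 0.23 (SE; adjusted p = 0.275 and 0.106). Cholesterol synthesis genes, 26 measured, had 0 past the test singly or adjusted over the list alone (camera adjusted p = 0.0708). Their median difference from wild type was 1.24 on knockout replicate 2 against 0.05 and -0.01 on replicates 1 and 3. The list passed upward on quantile normalization (adjusted p = 0.0133), on subtraction of array medians (adjusted p = 0.00474), without dim genes (adjusted p = 0.0456) and without knockout replicate 1 or 3 (adjusted p = 0.0440 and 0.0128). These used the preset correlation, and its adjusted p was 0.868 with an estimated correlation. Among 37 phospholipid synthesis genes Enpp2 rose, alone also when adjusted over the list alone (camera adjusted p = 0.835). Among 40 ABC transporters 0 passed singly or adjusted over the list alone (camera adjusted p = 0.647). The median and the mean differed in sign for the ABC transporters (-0.02 and 0.01) and the phospholipid list (-0.01 and 0.11).

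Contractile and myofibroblast genes lay lower on the arrays labelled knockout. None of 26 passed singly, 3 were lower when adjusted over the list alone, and the median log2 fold change was -0.59 (camera adjusted p = 0.000445; adjusted p = 0.655 with an estimated correlation). Ankrd1 had a log2 fold change of -3.52 ± 0.30 (SE; adjusted p = 0.0675). Among 42 fibroblast matrix genes the microfibril gene Mfap2 rose by 2.56 ± 0.14 (SE), with 4 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.437). Of 33 matrix proteases and inhibitors 0 passed, with 4 higher when adjusted over the list alone (camera adjusted p = 0.0708). Among 50 growth factor and transformation genes Igf1 rose and Igfbp2 fell, with 2 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.650).

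Genes of antigen presentation and inflammation lay higher as lists on the arrays labelled knockout, with 0 members past limma's test and, at an unadjusted p under 0.05, 4 and 9 higher. For 18 genes of MHC class I presentation the median log2 fold change was 0.30 (camera adjusted p = 0.00414; adjusted p = 0.585 with an estimated correlation), with 0 past when adjusted over the list alone. The estimated correlation of this list was -0.0124, below the preset 0.01, so correlation between members did not raise its p. For 35 inflammatory genes the median was 0.10 (camera adjusted p = 0.00594; adjusted p = 0.816 with an estimated correlation), and 2 were higher when adjusted over the list alone. The complement gene C3 had a log2 fold change of 2.89 ± 0.26 and the cytokine gene Il33 of 2.90 ± 0.25 (SE; adjusted p = 0.0677 and 0.0675). The call on MHC class I presentation ended without wild-type replicate 3 (adjusted p = 0.0708), and that on the inflammatory list without wild-type replicate 2 or 3 (adjusted p = 0.0603 and 0.0848). Among 44 interferon-stimulated genes 0 passed singly or adjusted over the list alone (camera adjusted p = 0.0599). They lay on the other side, with 30 lower and a median of -0.38. That list passed downward once chromosome medians were subtracted (camera adjusted p = 0.0134; adjusted p = 0.816 for all arrays with an estimated correlation). Its median difference from the wild-type mean was 0.33 and -0.33 on wild-type replicates 2 and 3, and -0.27, -0.46 and -0.41 on the knockout replicates. Among 32 genes of the unfolded protein and integrated stress response 0 passed singly or adjusted over the list alone (camera adjusted p = 0.495).

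**Figure D2:**
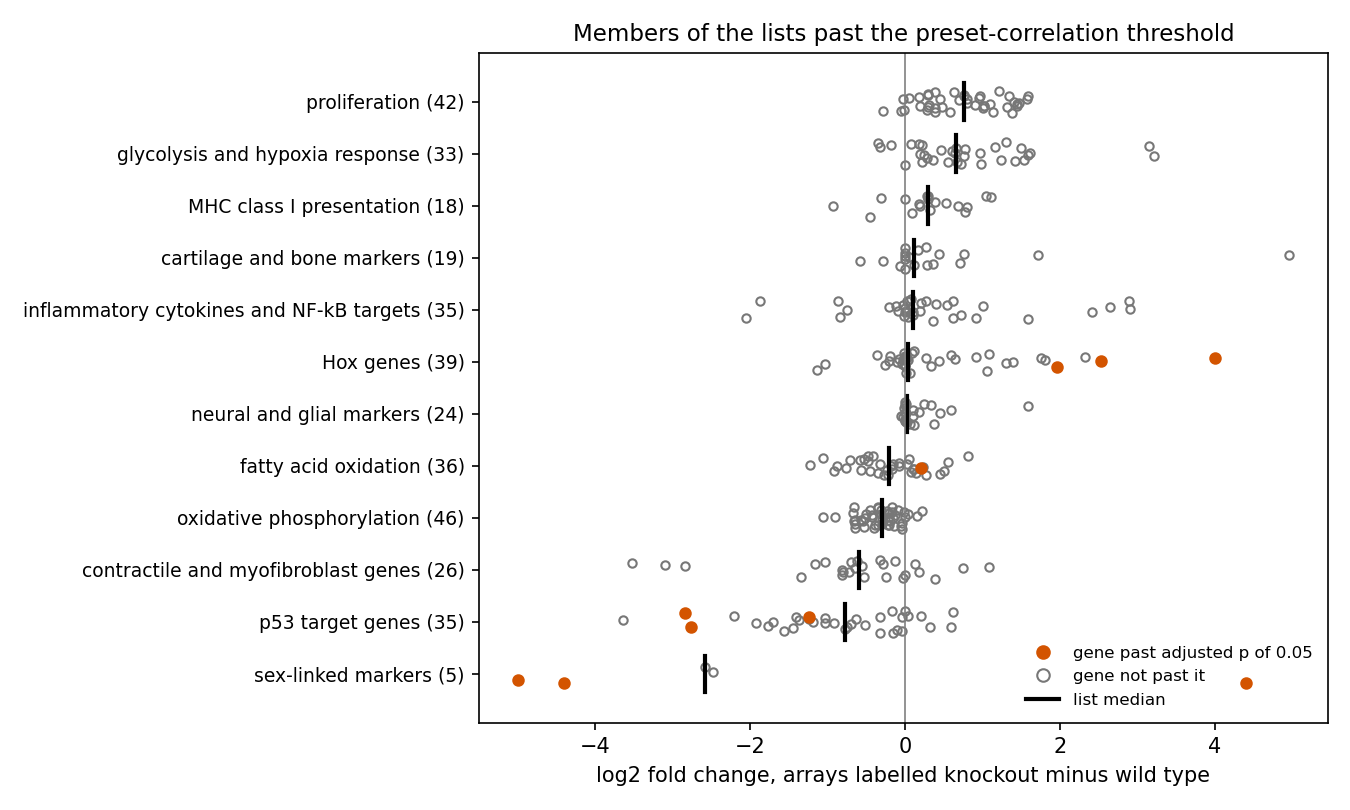
Log2 fold change, arrays labelled knockout minus wild type, of each measured member of the 12 gene lists past the threshold with the preset correlation, with list medians as vertical bars and the number of members in parentheses. Vertical scatter within a list carries no value; the p53 targets centre on -0.77 and the proliferation genes on 0.76, and filled points mark genes past an adjusted p of 0.05.

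Markers of most other cell types did not pass the test. Epithelial, endothelial, macrophage and leukocyte, and skeletal muscle markers had 0 members past the test, singly or adjusted over the list alone, and medians between 0.00 and 0.02 (camera adjusted p = 0.820, 0.493, 0.820 and 0.650). Of 18 adipocyte markers 0 passed, with 2 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.650). Of 19 cartilage and bone markers 0 passed, with 2 higher when adjusted over the list alone, and the list lay higher (camera adjusted p = 0.0151; adjusted p = 0.641 with an estimated correlation; adjusted p = 0.140 without wild-type replicate 2). The bone matrix gene Spp1 had a log2 fold change of 4.96 ± 0.36 (SE; adjusted p = 0.0586). Neural and glial markers lay higher with a median of 0.03, which turned to -0.01 on quantile normalization and on subtraction of array medians (camera adjusted p = 0.0439; adjusted p = 0.641 with an estimated correlation), and 0 of 24 passed singly or adjusted over the list alone. Its call ended on both scalings and without knockout replicate 1 or 3 or wild-type replicate 2 (adjusted p = 0.0915, 0.0655 and 0.209). The 5 sex-linked markers formed a shifted list too (camera adjusted p = 0.00414; adjusted p = 0.585 with an estimated correlation), with 1 higher and 4 lower when adjusted over the list alone. That list holds Xist and 4 Y-linked genes, so its shift restates the differences of the single genes and adds no support to them.

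Whole chromosomes differed between the groups, a question raised by the known tendency of passaged mouse fibroblasts to gain and lose chromosomes. Genes of chromosomes 1, 8 and 11 and the mitochondrial genome lay lower on the arrays labelled knockout, and genes of chromosomes 3 and 19 higher (camera adjusted p = 0.000323, 4.27e-05, 0.00210, 4.27e-05, 0.000323 and 0.0224, in that order). Chromosome Y was lower as well (adjusted p = 0.0406). The call on chromosome 19 ended without knockout replicate 2 or wild-type replicate 3 (adjusted p = 0.0935 and 0.148), and that on Y without knockout replicate 1 or 2 or either wild-type replicate (adjusted p between 0.0558 and 0.358). Among the brighter part of the genes, those above the median level, the median log2 fold change was -0.38 over 603 genes of chromosome 1, -0.26 over 607 of chromosome 8, -0.22 over 906 of chromosome 11 and 0.14 over 517 of chromosome 3. For chromosome 19 it was only 0.04 over 399 such genes. Their median difference from the wild-type mean was 0.02, 0.09 and 0.01 on knockout replicates 1, 2 and 3. With an estimated correlation none of the 22 chromosomes passed, with an adjusted p = 0.0529 for chromosomes 1 and 8, 0.0594 for chromosome 11, 0.0574 for chromosomes 3 and 19 and the mitochondrial genome, and 0.266 for chromosome Y.

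Of the genes past the test, 8 on chromosome 1 fell and 0 rose, as did 2 and 0 on chromosome 8, and 5 and 0 on chromosome 11, while 8 on chromosome 3 rose and 1 fell. The brightest on chromosome 1 were Igfbp2, Zc3h11a (-0.62), Rgl1 (-2.35) and Tns1 (-1.13). Other probe sets of Tns1 gave log2 fold changes from -1.39 to 0.01. On chromosome 8 Arhgap10 fell by 0.92 and Spg7 by 0.80, and on chromosome 11 Copz2 fell by 0.65, Supt6 by 0.44 and Arhgap23 by 0.91. On chromosome 3 Rbm8a rose by 0.51 and Slc39a1 by 0.53. Second, dimmer probe sets gave smaller log2 fold changes, -0.17 for Arhgap23 and 0.28 for Slc39a1. On chromosome 19 Erlin1 rose by 1.85 and Plce1 by 1.79, while Mamdc2 fell by 1.23.

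**Figure D3:**
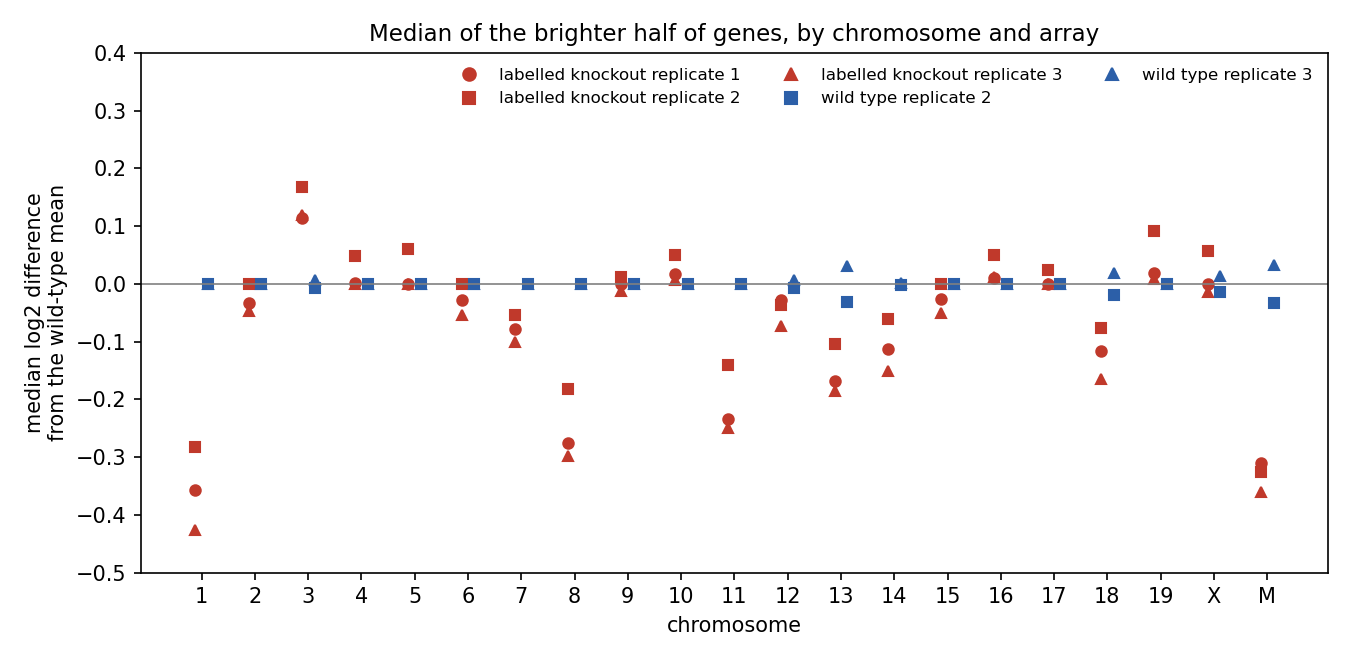
Median log2 difference from the wild-type mean over the genes above the median level, for each chromosome except Y and each of the 5 arrays. Centring on the wild-type mean holds the wild-type points near 0 by construction; the arrays labelled knockout lie between -0.28 and -0.43 for chromosome 1, -0.18 and -0.30 for chromosome 8, and 0.11 and 0.17 for chromosome 3.

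Genes flanking the targeted locus were compared with the rest of the genome, since flanking DNA can come from another strain. The 60 genes within 10 Mb of Abcb4 had a median log2 fold change of 0 (-0.14 over the 35 above the median level) and did not pass camera's threshold as a set. One of them, Gnai1, passed the gene-wise threshold, against 64 of 21570 genes elsewhere (two-sided Fisher exact p = 0.165).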

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

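The settings that leave out genes with equal values, keep only brighter genes or join a filter with trended and robust variances were chosen after seeing the data, as was the subtraction of chromosome medians, and all other settings were fixed before the data were examined. The count of 65 genes (46 at least 2-fold) became 363 (233) on a second quantile normalization, 250 (172) on subtraction of array medians, 270 (179) without dim genes, 107 (74) with array weights, 359 (249) without genes of equal values, 397 (254) above the median level, 526 (236) above a log2 mean of 6, and 330 (234) with the joined filter and variances. The causes were not tested. It was 0 at an adjusted p of 0.01. Leaving out 1 array gave 0 to 335 genes (0 to 65 at least 2-fold), and where a wild-type array is left out the lone one is assumed to vary like the other group. Trended or robust variances and the mean of all probe sets kept the count within 1.5 times but ended single calls that the report names beside the genes and lists, and robust variances were run for genes only. Abcb4 stayed higher and short of the threshold under every setting run for it, from 1.19 to 1.87. Of 34 lists, 12 passed with the preset correlation, 0 with an estimated correlation and 5 with fry. A call lost with an estimated correlation does not by itself show correlated members. The estimate was 0.79 for proliferation but -0.0046 for Hox genes. The lists past fry were the p53 targets, MHC class I presentation, Hox genes, imprinted genes and sex-linked markers. Proliferation and oxidative phosphorylation missed it (fry adjusted p = 0.337 and 0.201). Of 22 chromosomes 7 passed, against 12 without dim genes, 0 with an estimated correlation and 13 among brighter genes. For the genes near Abcb4, far from any threshold, camera's direction turned under several settings: their median, 0, became -0.0177 on quantile normalization, -0.0359 on subtraction of array medians, -0.0527 without dim genes, 0.0056 within 20 Mb and 0.0247 without genes of equal values, was 0 with the mean of all probe sets, and lay between 0 and 0.0094 with 1 array left out. Camera's direction also turned for lists with medians near 0. The median of the glutathione S-transferases became 0.0599 without dim genes and -0.0518 to 0.0381 with 1 array left out. Those of the ABC transporters (-0.0293 without dim genes) and the aldehyde and xenobiotic oxidoreductases (-0.0392 on subtraction of array medians) kept their sign. With 1 array left out the last lay between -0.0174 and -7e-04, phospholipid genes between -0.0259 and 0.0368, and oxidant-producing enzymes between 0 and 0.0462. The causes were not tested. Signal over background limits the dim genes, whose fold changes are compressed.

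With the replicate number as a block, 0 genes passed limma's test (0 at least 2-fold; 2319 at an unadjusted p under 0.05), the median near Abcb4 was 0 and that of the aldehyde and xenobiotic oxidoreductases -0.005. The block fit leaves knockout replicate 1 without a partner. The numbers do not show a pairing: the difference between replicates 2 and 3 correlated at -0.17 across genes between the groups, and genes are not independent replicates.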

Other observations

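The tests of exchanged arrays, turned labels, paralogues, regions within chromosomes, chromosome copies and p53 activity were chosen only after the result was seen, and so were the genes of the next paragraph.

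Several imprinted and positional genes had large log2 fold changes that missed the threshold. The imprinted Plagl1, Snrpn and Ndn had log2 fold changes of -3.03, -2.38 and -2.33 on the arrays labelled knockout (limma adjusted p = 0.0675, 0.0675 and 0.0598), and Mest and Slc38a4 of 3.33 and 2.90 (adjusted p = 0.155 and 0.106). Of the 16 genes of Hox groups 9 to 13, 11 were higher without overlap and 0 lower, with a median of 1.19, while of 23 genes of groups 1 to 8, 3 were higher and 4 lower. Of 15 positional transcription factors 0 passed the test. The hindlimb regulators Tbx4 and Pitx1 came nearest, with log2 fold changes of 4.28 ± 0.31 and 2.25 ± 0.16 (SE; adjusted p = 0.0582 and 0.0573), and both passed once genes with equal values on all arrays were left out (adjusted p = 0.0163 for each).

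Of all 21630 genes, 25% did not overlap between the groups, 2292 higher and 3116 lower on the arrays labelled knockout. The chance share is 20% for a gene with 5 distinct values, which 7670 genes had. Equal values lower it, so the chance share over all genes lies below 20% and was not computed. The real split of the 5 arrays gave 65 genes past the threshold and the highest of the other splits 0. Every other split mixes arrays labelled knockout with wild-type arrays, so the group difference enters the residual spread. Calls there were unlikely from the start, so the 0 adds no support for the 65 genes. The 10 splits are also too few for a share under 0.05. Knockout replicate 2 lay farthest from its group, with 282 genes at least 1 log2 unit from the other knockout replicates, against 177 and 88 for replicates 1 and 3.

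Abcb4 signal was higher on the arrays labelled knockout, against the label, and an exchange of single arrays between the groups is argued against, since 0 arrays were out of place by sex-linked markers or best correlation. Turned labels of both whole groups stay open: the log2 fold change of 1.457 is what they would give, and no second value depends on genotype alone. Binding of Abcb1a or Abcb1b transcripts to the Abcb4 probes also stays open, since the excess of Abcb4 over the nearer paralogue was 0.8853 with a standard error of 0.952. The values per array run against it without deciding it: Abcb1a and Abcb1b were highest on knockout replicate 2 (4.369 and 6.206), where Abcb4 had its lowest knockout value (4.628). A remaining transcript outside the disrupted part may also be read by the probe set, and a signal near background may differ by noise, and neither was tested.

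Genes of chromosomes 1, 8 and 11 lay lower on the arrays labelled knockout, and a brightness-dependent scaling is argued against, since the highest of the chromosome medians after subtraction of the trend was -0.1717. A few regions are argued against as well, since 100% of the 10 Mb windows with at least 20 brighter genes had medians below 0 (15, 11 and 12 windows). Of the windows with fewer such genes, 1 on chromosome 1 (1 gene) and 1 on chromosome 8 (2 genes) lay above 0. Fewer copies of these chromosomes stay open: every knockout array lay below both wild-type arrays on all 3, but they were picked for that shift, so this supports no cause over another. Base composition was not tested, and copy number was not measured here.

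Targets of p53 lay lower on the arrays labelled knockout, with Cdkn2a at a log2 fold change of 1.99. The list's median was -0.7152 after subtraction of the brightness trend and -0.7968 after subtraction of chromosome medians, which argues against either as the whole cause. Lower p53 activity stays open: 21 targets were lower and 3 higher on every knockout array than on both wild-type arrays, which restates the shift of the list and adds no support. Whether the shift goes with genotype, sex or the history of separately passaged cultures cannot be read from these groups.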
